A study of Mus musculus with 8 samples.

How the data were processed

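Total RNA of minced left and right atria of adult male mice was amplified and labelled with Cy3 or Cy5 for Agilent two-colour arrays, per the labels' protocols. The samples fall into 2 groups, left atrium and right atrium, with 4 biological replicates each. Replicates 1 and 2 of a side shared 1 array and replicates 3 and 4 another, with replicates 1 and 3 in Cy3 and replicates 2 and 4 in Cy5, per the labels. All 4 arrays lay on 1 slide, the left atrium at positions 1 and 2 and the right atrium at positions 3 and 4. Whether left and right samples with the same number came from the same mouse is not given in the sources used here.

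The deposited table holds log2 values, 1 column per sample, each with a median of 0. The scans were read with Agilent Feature Extraction, per the submitters' processing notes, and each channel was processed on its own, per the series' design text. The background correction, the flag filter and the rule that left cells empty are not given in the sources used here. The base and the centring were settled from the values: 2 raised to each value, times 1 constant per column, gave whole numbers for 100% of the values (tolerance 0.01), so the authors divided whole intensities by the column median and took log2. The intensity that corresponds to a column's median was 206 to 304 units in the Cy3 samples and 319 to 707 in the Cy5 samples. The lowest intensity in a column was 32 to 51 units. Entries are numbered features, from 1 to 45220, of which 823 numbers are not listed. Numbers without any value recurred in blocks at a spacing of 85, so a feature's row and column on the array were taken from its number with 85 columns and 532 rows. No table used here pairs these numbers with genes. The analysis therefore ran on single features, and the plans made for genes (a panel of 19 marker genes, 38 gene lists and the naming of up to 12 genes per direction) could not be applied.

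The test and its alternatives were fixed before the data were examined, except where the text says otherwise. Features with a value in all 8 samples were kept. The rule fixed in advance called for quantile normalization if the column medians differed by more than 0.25. The deposited medians are all 0, but they are taken over different features in each column. Over the 30023 features that entered the fit the medians differed by 0.97, so the values were quantile-normalized across the 8 columns, and the values as deposited were kept as an alternative. This choice was made after the medians and before any test was seen. Left and right atria were compared with limma (version 3.58.1, R version 4.3.3, statmod version 1.5.0): lmFit with side and dye as fixed terms, array as a random block through duplicateCorrelation, and eBayes with an intensity trend. The consensus correlation within arrays was 0.51, the residual degrees of freedom were 5 and the prior degrees of freedom 2.47. That fit assumes the same correlation for every feature. P-values are two-sided and were adjusted by Benjamini-Hochberg over all tested features, and a feature was called at an adjusted p under 0.05. Values are given as log2 of the intensity over the column median, and differences as left minus right. Because the gene rule could not be used, the text names the 2 called features with the largest difference in each direction whose 4 samples of one side all lay above those of the other. Array values are the means of the 2 samples of an array. No array or sample was left out of the main comparison.

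The fit was tested on simulated data for this comparison, with 30023 features, the real means and residual SDs, a correlation of 0.5 within arrays and 200 changed features in each of 3 runs. With the array block, 60.0% of features changed by 1 on the log2 scale and 89.3% of those changed by 2 were recovered, and 6.26% of the calls were false. Without the array block, 27.6% of the calls were false. With array means, 0% and 51.0% were recovered and 6.27% of the calls were false. The simulated noise was normal with the same correlation for every feature, as the fit assumes, and held no features high on a single array. These false shares therefore need not hold for the real calls.

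Whether the replicate numbers pair the samples was checked from the deviations of same-numbered left and right samples from their side's mean. The correlations across features were 0.05, 0.07, 0.05 and 0.05 for replicates 1 to 4. Same-numbered samples also carried the same dye, and from the mean of side and dye the correlations were 0.02, 0.01, 0.02 and 0.01. With 2 samples per side and dye, replicates 1 and 3 give the same value by arithmetic, as do replicates 2 and 4. All lay under the limit of 0.1 set for pairing, and the samples were treated as unpaired. Differences between arrays also enter these deviations and can hide a pairing, so the low values do not exclude it. The alternatives were other scalings, fits without the dye term or the array block, a replicate block, each dye alone, filters on dim features, other variance priors, features with at least 3 values per side, a fold threshold of 1.5, and leaving out each sample. A gene-wise mean of probes and a log offset did not apply. After the data were seen, the subtraction of a local surface trend, the use of array means and the leaving out of each array were added. The surface trend of a sample is the median deviation of the neighbouring spots, 3 or 5 spots each way, from the mean of all samples. In a further version it was taken only from spots of the same brightness class (each of 25% of the features), 6 spots each way.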

Results

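The atria are the thin-walled receiving chambers of the heart. The right atrium takes in systemic venous blood and holds the sinoatrial node, and the left atrium takes in blood from the pulmonary veins. Transcript levels were measured in the minced left and right atria of adult male C57Bl/6j mice, with 4 biological replicates per side, on 4 Agilent arrays of 1 slide. Each array carried 2 replicates of the same side, one labelled with Cy3 and the other with Cy5, and each channel was treated as a sample of its own. The arrays therefore give 8 samples but 2 independent hybridisations per side. The deposited table lists 44397 array features by number, and neither it nor the gene table used here pairs a feature number with a transcript. Features are therefore reported by number and position on the array, and no gene, pathway or cell type is named.

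Signal was read for 42766 to 42922 features in the 4 Cy3 samples and for 33186 to 37779 features in the 4 Cy5 samples. The fewest were in right atrium replicate 4 and the most among the Cy5 samples in left atrium replicate 4. All 8 samples had a value for 30023 features, which entered the comparison of the sides. A further 12997 features had a value in some samples only, and 1377 had none in any sample. The linear intensities recovered from the table were whole numbers, and the median feature of a sample corresponded to 206 to 707 intensity units. Within each dye this median was higher in the right atrium. It was 285 and 304 units against 219 and 206 in the left atrium in Cy3, and 513 and 707 against 412 and 319 in Cy5. The number of arrays limits the precision of the comparison.

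Each sample correlated best with the other sample of its array, and the correlations between samples of different arrays overlapped between the same side and different sides. After quantile normalization, the Pearson correlation across features was 0.992 to 0.995 for the 4 pairs of samples on the same array. It was 0.969 to 0.981 for the 8 pairs from the same side but different arrays, with a median of 0.973, and 0.956 to 0.977 for the 16 pairs from different sides, with a median of 0.970. Summed over all tested features, the side accounted for 37.4% of the sum of squares, the array within a side for 48.4%, the dye for 5.41% and the remainder for 8.80%. Arrays are nested within sides, so the share of the side also holds differences between arrays. Per degree of freedom, the mean square was 0.455 for the side, to be set against 0.295 for the array within a side. It was 0.0357 for the remainder. The medians over features were lower, at 0.0767 for the side, 0.0343 for the array within a side and 0.0125 for the remainder.

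The first question was which transcripts differ between the left and the right atrium. Of the 30023 features tested, 858 differed between the sides (2.86%, limma with dye as a fixed term and array as a random block, Benjamini-Hochberg adjusted p under 0.05). Of these, 518 were higher in the right atrium and 340 in the left atrium. In all 858, the 4 samples of one side lay above the 4 samples of the other, and such separation occurred in 6917 of all tested features (23.0%). Chance gives 2.86% for 8 independent samples, but samples of one array are not independent, and the other two splits that keep arrays whole separated 1519 features (5.06%, replicates 1 and 2 against 3 and 4) and 1418 features (4.72%, crossed). The difference reached 1.5-fold in 736 of the called features, 2-fold in 357 and 4-fold in 50. The median size of a called difference was 0.91 on the log2 scale for features higher in the left atrium and 0.87 for features higher in the right atrium. With the values as deposited, the split changed to 353 features higher in the right atrium and 780 in the left atrium, and the median left minus right difference of all features was 0.15 on the log2 scale instead of -0.006. The split was 406 in the right atrium against 353 in the left with median centring, and 489 against 362 with quantile normalization within each dye. After subtraction of the surface trend it was 709 against 565. Among these scalings the balance of directions turned only with the values as deposited, so it is relative to the scaling used.

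The largest log2 difference among the called features was at feature 11367 (array row 134, column 62). Its log2 level was 7.80 ± 0.07 (SD, n = 4) in the right atrium and 2.51 ± 0.26 (SD, n = 4) in the left atrium. This is a 39.0-fold higher level in the right atrium, with a log2 difference of left minus right of -5.29 ± 0.20 (SE, limma adjusted p = 0.000123). Feature 28343 (row 334, column 38) was 18.5-fold higher in the right atrium, with log2 levels of 4.41 ± 0.37 on the right and 0.21 ± 0.41 on the left (SD, n = 4, limma adjusted p = 0.00136). Higher in the left atrium were feature 2300 (row 28, column 5) and feature 39696 (row 468, column 1). Feature 2300 had a log2 level of 4.89 ± 0.98 in the left atrium and 1.44 ± 0.76 in the right atrium (SD, n = 4), a 10.9-fold difference with a limma adjusted p of 0.0232. It was no longer called in 12 of 30 alternative settings, and its left minus right difference was 2.00 between the arrays of replicates 1 and 2 and 4.90 between the arrays of replicates 3 and 4. Feature 39696 had a log2 level of 4.69 ± 0.52 in the left atrium and 1.90 ± 0.23 in the right atrium (SD, n = 4), a 6.92-fold difference with a limma adjusted p of 0.0125. With array means as the unit, the limma adjusted p was 0.0412 for feature 11367 and 0.0877 for feature 28343. It was 0.224 for feature 2300 and 0.111 for feature 39696. The adjacent features with a value, between 4 and 6 in number for each of these positions, had median left minus right differences between -0.20 and 0.16 on the log2 scale.

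**Figure D1:**
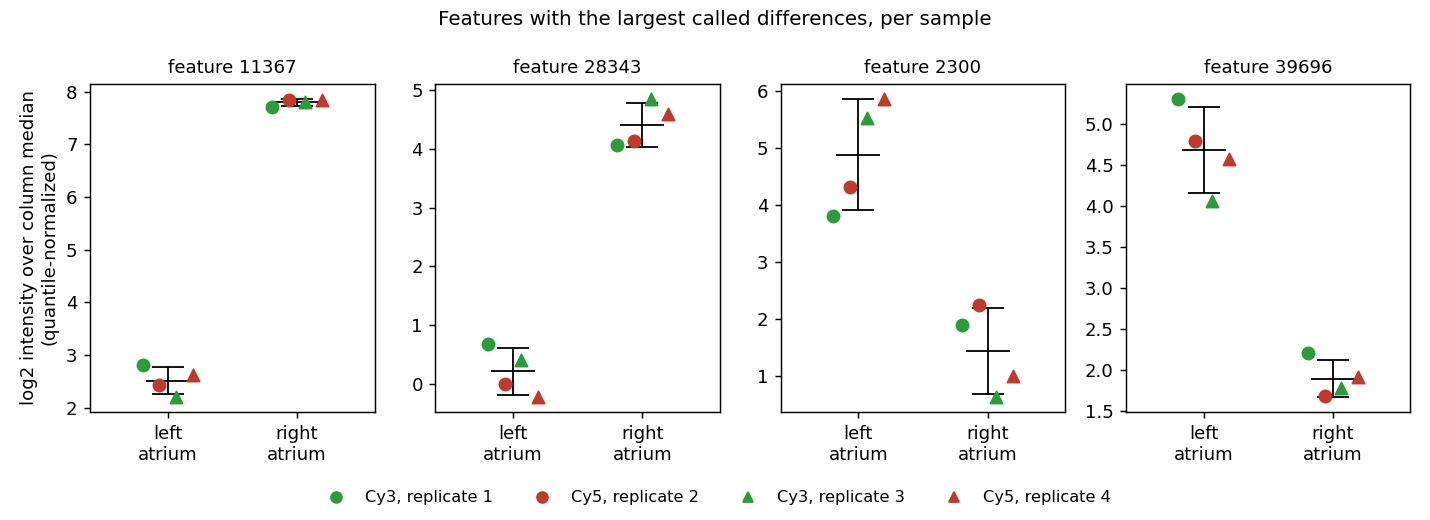
Log2 intensity over the column median after quantile normalization (vertical axis) of the 2 called features with the largest fold towards each side, for the 4 left and 4 right atrium samples. Points are samples, coloured by dye and shaped by array (circles replicates 1 and 2, triangles replicates 3 and 4), with the mean and SD as bars (the vertical scale differs between panels); in each panel the 4 samples of one side lie apart from those of the other, and for feature 2300 the samples also split by array.

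With all 4 arrays, most features with very large differences were higher in the right atrium. Of the 50 features called with a difference of 4-fold or more, 33 were higher in the right atrium and 17 in the left. Of the 13 called at 8-fold or more, 12 were higher in the right atrium and 1 in the left. With the values as deposited, 31 features higher in the right atrium and 26 higher in the left atrium were called at 4-fold or more, and 11 and 2 at 8-fold or more. The counts at 8-fold or more turned with single arrays. Without the left array of replicates 1 and 2 or of replicates 3 and 4 they were 114 and 79 higher in the left atrium against 18 and 15 in the right, and without the right array of replicates 1 and 2 or of replicates 3 and 4 they were 1 and 5 in the left against 82 and 89 in the right. At 4-fold or more, 231 and 152 were higher in the left atrium against 45 and 31 in the right without a left array, and 21 and 29 in the left against 173 and 204 in the right without a right array, in the same order. Of the features called at 8-fold or more in these comparisons, 80.9% to 84.8% were 4-fold or more above the other 3 arrays on the array left alone on its side. Among the called features with a difference of 2-fold or more, 59.4% were higher in the right atrium, and this share fell to 37.3% with the values as deposited.

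The second question was how far the differences between the sides recurred in separate hybridisations. The left minus right difference was therefore formed once from the arrays of replicates 1 and 2 and once from the arrays of replicates 3 and 4, which share no sample. Across the 30023 features, which are not independent replicates, the Spearman correlation of the 2 differences was 0.38, and 64.7% of features had the same sign in both. The same calculation within the sides, replicates 1 and 2 minus 3 and 4 in the left atrium against the right atrium, gave a correlation of 0.02 and the same sign in 51.1%. At 2-fold or more in both pairs, 150 features were higher in the left atrium, 232 were higher in the right atrium and 63 moved in opposite directions. With the arrays of the sides paired crosswise these counts were 156, 217 and 99, and for the comparison within the sides they were 29 and 72 in the same direction and 47 in opposite directions. At 8-fold or more in both pairs, 1 feature was higher in the left atrium and 11 in the right atrium.

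**Figure D2:**
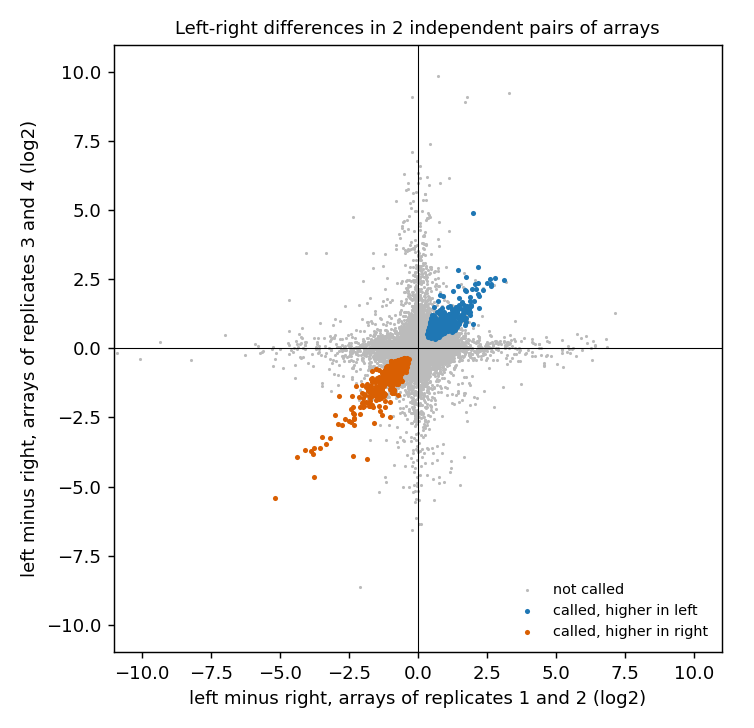
Left minus right log2 difference of each of the 30023 features between the arrays of replicates 1 and 2 (horizontal axis) and between the arrays of replicates 3 and 4 (vertical axis). Grey points are features that were not called, blue and orange points are features called as higher in the left or the right atrium. The called features lie along the diagonal, while many uncalled features differ by several log2 units in a single pair and lie along the axes. The calls were made from the same samples and favour a small spread within a side, so this arrangement is no separate evidence for them.

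Counted without any model, both arrays of one side lay 2-fold or more above both arrays of the other side for 316 features. In 191 of these the right atrium was higher and in 125 the left atrium. The other 2 ways of splitting the 4 arrays into 2 and 2 gave 76 features (replicates 1 and 2 against 3 and 4) and 38 features (crossed). At 8-fold or more the real split gave 11 features, all higher in the right atrium, and the other splits gave 0 and 1. With only 3 ways to split the 4 arrays, no permutation of whole arrays can reach a share under 0.05. When the samples of each array were averaged and 2 arrays were compared with 2, limma called 10 features, all higher in the right atrium and all also called above, and 4612 features had an unadjusted p under 0.05. Feature 11367 was among the 10, and features 28343, 2300 and 39696 were not.

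The called features were spread over the brightness range but were fewest among dim features. In the dimmest 25% of features 65 were called (0.866%), of which 50 were higher in the right atrium. In the second 25% 228 were called (3.04%), in the third 298 (3.97%) and in the brightest 267 (3.56%), of which 165 were higher in the right atrium. The median standard error of the left minus right difference was 0.17 on the log2 scale in the dimmest 25% and 0.12 in the brightest 25%.

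Each dye carried both sides, so the comparison was also made within each dye, with 2 samples per side. In the Cy3 samples alone limma called 0 features, with 3283 at an unadjusted p under 0.05, and in the Cy5 samples alone it called 4, all higher in the right atrium, with 4868 at an unadjusted p under 0.05. The log2 difference of feature 11367 was -5.25 in Cy3 and -5.32 in Cy5, and that of feature 2300 was 3.42 in Cy3 and 3.48 in Cy5. The number of called features also changed when single samples were left out. Without left atrium replicate 2, 3 or 4 the number was 200, 452 and 243. Without right atrium replicate 1, 2, 3 or 4 it was 542, 189, 359 and 461, and without left atrium replicate 1 it was 762. Left and right arrays also occupied different positions on the slide, so position and side cannot be told apart.

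**Figure D3:**
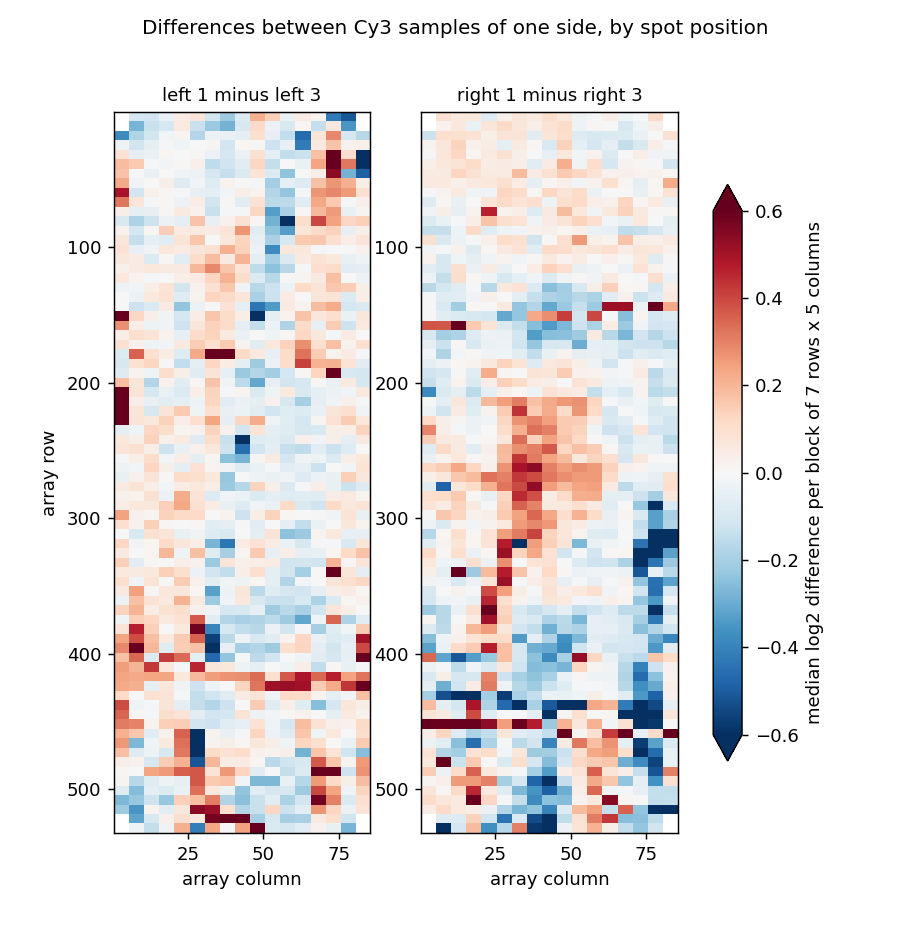
Median log2 difference between the Cy3 samples of the 2 left arrays (left panel) and of the 2 right arrays (right panel) in small blocks of spots, drawn at each block's array row (vertical axis) and array column (horizontal axis), with values beyond the colour scale drawn in its end colours. Samples of the same side differed in connected patches and streaks of the array and not only at single spots.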

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

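Of the tests in this part, the one of the surface trend against the resemblance of samples on an array was chosen after its result was seen, as were the settings that subtract a surface trend, average the samples of an array or leave an array out. None of the 16 groups of 4 values tested (the 4 named features and 4 measures per sample, by side) held a sample beyond Dixon's limit. Each group held 2 samples per dye and 2 per array, and values that fall in such pairs make a single outlier hard to flag.

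Signal also appeared among features left out of the comparison for empty cells. A value stood in both left Cy5 samples and in neither right Cy5 sample for 938 features, and in both right and neither left for 283. In the Cy3 samples these counts were 3 and 1, and 0 features had a value in all 4 samples of one side and in none of the other. In the Cy3 samples of the same arrays, 99.3% of 909 features with Cy5 values in the left atrium only were higher in the left atrium (median left minus right 0.43 on the deposited log2 scale), against 62.6% (median 0.12) of all features with 4 Cy3 values. Of 271 features with Cy5 values in the right atrium only, 46.5% were higher in the left atrium in Cy3 (median left minus right -0.12). The deposited scale divides by the column median, which in Cy3 was 219 and 206 units on the left and 285 and 304 on the right. An equal intensity therefore takes a higher value on the left, and the set of all features was not matched for brightness. Scaling and side cannot be told apart here, and these differences were not tested.

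The first pattern is the set of 858 features called between the sides. Of the 35 splits of the 8 samples into 4 and 4, 1 called as many features, the real split with 829 (correlation estimated on 10000 features), and the highest other was the split by dye with 436, but 32 of the 35 splits divide arrays whose samples resemble each other, so this count does not settle whether chance is excluded. Of the called features, 34.2% lay in the dimmest 50% by the mean of all 8 samples. This argues against features dim on both sides as the whole source. Features dim on 1 side only rank higher by that mean, and features with empty cells were not tested, so dim spots stay open there. Of the 858, 84.0% or more were still called in the same direction under 3 ways of subtracting the surface trend. This argues against that trend as the whole source. In the dim features neighbouring spots kept a correlation of 0.22 with the window of 3 and 0.17 within brightness classes (0.33 before). In the bright features it was 0.13 and 0.10 (0.26 before), so surface signal that was not subtracted stays open. For the set as a whole, differences between arrays unrelated to side cannot be told apart from the side by splits, because only 3 keep arrays whole, too few for a share under 0.05 (829 for the real split, 0 for the higher of the other two), and limma on array means, where arrays are the unit, called 10 of the 858. A difference in expression between the atria stays open beside a difference tied to slide position, and for the features not called from array means also beside differences between arrays.

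The second pattern is that samples on one array resembled each other and that each array had features far above the other 3. The consensus correlation within arrays was 0.51 after quantile normalization, 0.55 with median centring, 0.52 with quantile normalization within each dye and -0.03 with the values as deposited. After quantile normalization it kept 81.8% of its value after the surface trend was subtracted, in the test chosen after its result was seen. This argues against the subtracted trend as the whole source of the resemblance. The value of 0.57 in the brightest 25% of features argues against dim spots as the whole source. After subtraction within brightness classes, neighbouring spots still correlated in the left minus right difference (0.17 in dim and 0.10 in bright features). Surface signal that was not subtracted therefore stays open for the resemblance. A level 4-fold or more above the other 3 arrays was found for 130 and 200 features on the left arrays (replicates 1 and 2, replicates 3 and 4) and 142 and 128 on the right arrays. None of them was among the 858 called by limma. They differ 4-fold or more between the arrays of their own side, which makes a call unlikely, so this says little about the 858. Of these 600, 98.8% were 2-fold or more above in both dyes, which argues against a single dye channel. Of the 600, 47% touched another feature of the same set, against a mean of 1.39% and a maximum of 4.33% over 1000 permutations of positions, so patches on the array surface may account for many of them. Dim spots stay open for these 600, of which 91.2% lay in the dimmest 50% by the mean of the other 3 arrays. The 98.8% also argue against a difference in a single sample of an array. Differences shared by the animals or RNA preparations of an array stay open and were not tested.

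The third pattern is that the larger called differences were mostly higher in the right atrium, 59.4% at 2-fold or more. The share was 37.3% with the values as deposited, so the scaling between samples may account for it, but 55.1% with median centring, 59.0% with quantile normalization within each dye and 58.5% after subtraction of the surface trend. It was 34% without the left array of replicates 3 and 4 and 34.1% without the left array of replicates 1 and 2, against 72.1% and 70.1% without the right array of replicates 1 and 2 or of replicates 3 and 4. Leaving out an array can let features high on the array left alone on its side be called. Of the calls at 2-fold or more, 13.8% to 27.0% were 4-fold or more above the other 3 arrays on that array. A level 2-fold or more above was found for 35.4% to 44.5%. The share moved towards the thinned side in all 4 cases, so whether a single array accounts for it cannot be told apart from the side. A biological difference between the atria stays open for these features.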

How the results depend on the processing

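Of the settings in this part, those with a surface trend, array means or an array left out were chosen after the data were seen. Without the array block 4072 features were called in place of 858, and with the replicate block in place of dye and without the array block 2902, all 858 among them in both. The replicate numbers, which share a dye, correlated weakly (0.05 to 0.07, and 0.01 to 0.02 from the mean of side and dye). From their side's mean, left replicates 1, 2 and 3 correlated best with the right sample of their own number, and left replicate 4 with right replicate 2. Same-numbered samples share a dye, so this does not settle whether they are paired. Averaging the samples of each array left 10 calls, or 13 after subtraction of the surface trend. The Cy3 samples alone gave 0 calls by limma (3283 at an unadjusted p under 0.05) and the Cy5 samples alone gave 4. Without the dye term the number was 1384, and with at least 3 values per side it was 466 of 35354 tested. Subtracting the surface trend gave 1274, 1202 with the wider window and 1466 within brightness classes. Leaving out 1 sample gave 189 to 762 calls, and leaving out 1 array gave 651 to 2492, with 1297 and 2492 for the right arrays of replicates 1 and 2 and of replicates 3 and 4. Without left atrium replicates 2, 3 and 4 it was 200, 452 and 243, and without right atrium replicates 1 to 4 it was 542, 189, 359 and 461. The values as deposited gave 1133 calls (353 higher in right, 780 in left, 560 shared with the 858 in the same direction), median centring 759 (406 and 353), and quantile normalization within each dye 851. Filters on the dimmest 25% and 50% gave 953 and 778, other variance priors 807 and 906, and the added fold threshold of 1.5 gave 736. The cause of these shifts was not tested. Over 30 alternatives none of the 4 named features changed direction. They were chosen for large differences with the samples of one side all above the other, so a reversal was hardly possible and this is no separate evidence. Feature 11367 lost significance in 1, feature 28343 in 4, feature 39696 in 5 and feature 2300 in 12. The gene lists, the marker panel and the mean of a gene's probes were not run, because features carry no gene names here, and the log offset did not apply to log2 values.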

Other observations

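All comparisons in this part were chosen after the data were seen. Differences between 2 samples were shared by neighbouring spots. For left atrium replicate 1 minus replicate 3, the Spearman correlation between spots in adjoining rows of the same column was 0.23, and for right atrium replicate 1 minus replicate 3 it was 0.31. Between spots far apart in the order of features both correlations were 0.02. The mean level over all samples, by contrast, had a correlation of 0.03 between adjoining rows. The local trends of the 2 samples on an array correlated at 0.59 to 0.75 across spots. The trend was widest in right atrium replicate 1, with a 5th to 95th percentile range of -0.29 to 0.20 on the log2 scale, and narrowest in right atrium replicate 4, from -0.12 to 0.11. Of the called features, 4.78% had an adjacent called feature of the same direction, against a mean of 3.87% over 1000 permutations of positions (permutation p = 0.2).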
